A study of Mus musculus with 32 samples.

How the data were processed

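PolyA RNA was sequenced from sorted mouse intestinal stem cells (Lgr5-eGFP high) and progenitors (Lgr5-eGFP low), both gated as EpCAM-positive and negative for CD31, Ter119, CD45 and 7AAD. The mice were wild type (Cre drivers only) or Cpt1a-deficient (floxed Cpt1a with the same drivers), on a high-fat diet or a high fat control diet. The 8 groups held 4 libraries each, 32 in all, and the labels give 2 female and 2 male libraries per group.

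Per the submitters' processing notes, the reads were processed with tools that include STAR 2.5.3a, RSEM 1.3.0 and SAMtools 1.3 on mm10. The notes give no role or order for the tools, and no annotation or strand setting. The deposited expected counts are estimated read counts per gene for 50686 Ensembl genes, rounded to whole numbers. That they were fractional before rounding was read from 2831 values at a count of 0 with a TPM above 0. The second deposited table holds log2 values, namely the log2 of TPM plus 1 for the same genes and libraries, and TPM had the same sum in each library to within rounding. Symbols came from a table of gene names, which named 50376 of the 50686 genes, and positions from GENCODE M21, which held 50462 of them. Genes without a symbol held 0.0677% of the counts.

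Library totals ran from 3307711 to 7337425 estimated counts with a median of 5655066.5, and the correlation between replicate libraries in log2 CPM was 0.961 to 0.983. The tests were tried on simulated data with the same depth and groups. For the diet effect in wild-type stem cells edgeR recovered 44% of genes changed 1.5-fold, 70% changed 2-fold and 88% changed 4-fold, with 8 false among 158 calls. DESeq2 had 20 false among 176 calls and limma 7 among 159. limma was tried here on the log2 of unscaled CPM plus 1, not on TPM, on which it was run for the real data. For the interaction in stem cells edgeR recovered 18%, 50% and 76%. A gene that did not pass is therefore not shown to be unchanged, also where its change is 2-fold or more. In the real data edgeR called 31 genes for this diet effect, and the simulated noise was independent between libraries, so real recovery may be lower.

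The columns of both tables carry the group of each library but no replicate number or sex, so libraries are called a to d in the order of the columns. The sex covariate planned for each model, the block by labelled replicate number, the fits of female or male libraries by label and the left-out replicate numbers could therefore not be fitted from the labels, and the reported models have no sex term. In each group, libraries a and b had more Xist than Ddx3y and libraries c and d the opposite, so a term read from these genes was possible, and the Xist level as a covariate took its place among the alternatives.

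Genes were tested in edgeR 4.0.16 with TMM scaling, filterByExpr at its minimum count of 10, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. Stem cells and progenitors were fitted apart, with 16 libraries and 4 groups each, for the diet effect in each genotype, the genotype effect on each diet and their interaction. All 32 libraries were fitted together for stem cells against progenitors and for the differences of the diet and genotype effects between them. The filter left 12409 genes in stem cells, 12460 in progenitors and 13088 in the joint model. The standard error is the absolute log2 fold change over the square root of the quasi-likelihood F. CPM in the text is TMM-scaled.

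Lists of genes covered fatty acid and energy metabolism, cell type markers, signalling, stress and immune genes, 39 lists in all. They were written from general knowledge, and like the comparisons, tests and most alternatives they were fixed before the data were examined. A list was tested with fry in limma 3.58.1 when at least 5 members passed the filter, which held for 36 lists, and its p was adjusted over these. Markers of white blood cells, of stroma and endothelium and of red blood cells had too few expressed members. Fry asks whether the members move one way on balance and does not compare a list with other genes. camera with an estimated correlation and with its preset correlation were the alternatives.

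Genes named in the text followed a rule. Cpt1a, Cpt1b and Cpt1c were always looked at. From each list up to 4 members with the smallest adjusted p under 0.05 were eligible, or up to 2 with the smallest p where none passed. Up to 10 genes higher and 10 lower with the largest change were eligible if their adjusted p was under 0.05, their mean log2 CPM at least 3 and the libraries of the 2 groups did not overlap, which chance gives for 2.86% of genes in a comparison of 4 with 4 libraries. The overlap condition was not applied to interactions or to stem cells against progenitors. Lgr5, Epcam, Cd24a, Ptprc and Pecam1 bear on the sort and served as checks of it. Not every eligible gene is named.

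Effects that share libraries are correlated without any change, so their correlation across genes was compared with 500 simulated sets of unchanged groups and with the shared libraries split into 2 and 2.

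Alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR, limma with a trend on the deposited log2 TPM values, no filter, a filter of 50 counts in 4 libraries, protein-coding nuclear genes only, all 32 libraries in 1 model, only the 8 libraries compared, and each library left out in turn. Chosen after seeing the data were the column set as a block (the 4 runs of 8 consecutive library numbers in the column names, each with 1 library of every group, called a to d), the same set within each diet and genotype as a block for the joint model, the Xist level as a covariate, a score of secretory markers as a covariate in stem cells, and the diet effect within libraries with Xist and within those with Ddx3y. The computing used R 4.3.3, the data.table package (1.17.8), Python 3.11.15 and matplotlib 3.10.9.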

Results

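PolyA RNA was sequenced from mouse intestinal crypt cells sorted into Lgr5-eGFP-high stem cells and Lgr5-eGFP-low progenitors. The mice were wild type or carried floxed alleles of Cpt1a, which encodes the enzyme that admits long-chain fatty acids to mitochondria, together with an intestinal Cre driver. They ate a high-fat diet or its control diet. Each of the 8 groups of cell population, genotype and diet held 4 libraries, 32 in all, and the labels give 2 female and 2 male libraries per group. The library totals ran from 3307711 to 7337425 estimated counts, with a median of 5655066.5, and no single gene took more than 1.43% of a library. In every group, 2 libraries had more Xist than Ddx3y reads and 2 had the opposite.

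Cpt1a (ENSMUSG00000024900; GRCm38 chromosome 19, 3322334 to 3385733) was low in each Cpt1a-deficient library. Wild-type stem cell libraries held 119.5 to 240.2 TMM-scaled counts per 1e6 (CPM) and deficient ones 18.7 to 25.7 CPM. In progenitors the ranges were 169.8 to 342 CPM in wild type and 18.9 to 31.0 CPM in deficient cells. By edgeR's quasi-likelihood test, the deficient stem cells had 8.67-fold less Cpt1a on the high-fat diet (log2 fold change -3.12 ± 0.14 SE, n = 4 and 4, adjusted p = 2.19e-10) and 6.76-fold less on the control diet (-2.76 ± 0.14, adjusted p = 1.64e-09). The deficient progenitors had 10.6-fold less on the high-fat diet (-3.41 ± 0.17, adjusted p = 3.77e-09) and 8.43-fold less on the control diet (-3.07 ± 0.17, adjusted p = 1.71e-08). The paralogs Cpt1b and Cpt1c reached at most 1.04 and 1.42 CPM in any library. Counts over the whole gene cannot tell an intact transcript from one that lacks the floxed part.

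**Figure D1:**
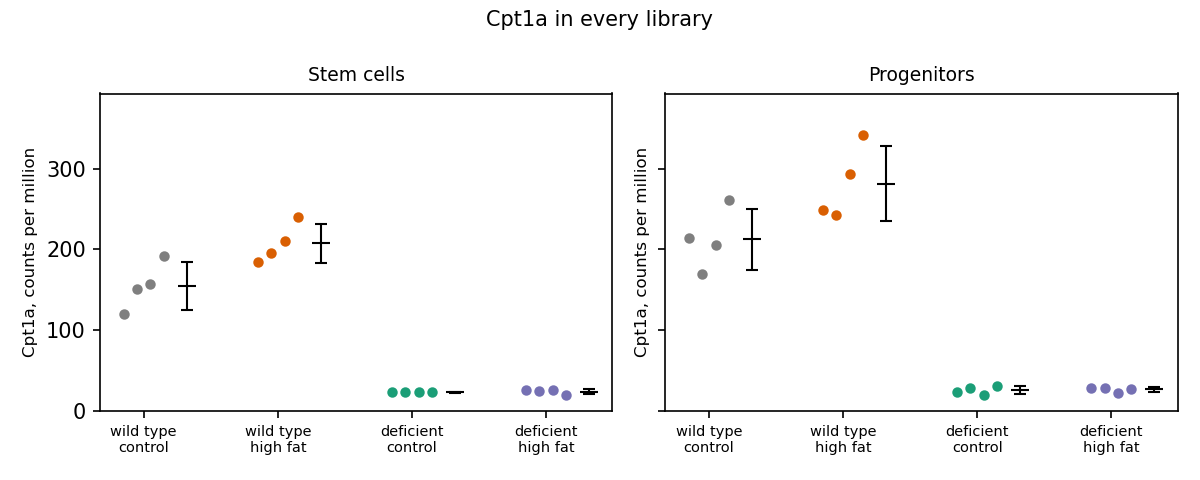
Cpt1a in CPM (vertical axis) in every library of the 8 groups (horizontal axis), with each point 1 library and the bar beside it the mean and SD of 4 libraries. The highest deficient library, at 31.0 CPM, lies under the lowest wild-type library, at 119.5 CPM.

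The 16 stem cell libraries were compared with the 16 progenitor libraries to describe the 2 sorted populations. Stem cells held more mRNA for the crypt base genes Smoc2 (log2 fold change 1.35 ± 0.06 SE), Olfm4 (2.09 ± 0.11), and Tnfrsf19 (2.93 ± 0.15), and for Clu (3.34 ± 0.28). Of 28 tested stem cell markers, 27 were higher in stem cells and 1 did not pass, 27 and 0 adjusted over the list alone (median log2 fold change 1.3, fry adjusted p = 3.93e-16). Progenitors held more of every tested goblet cell marker, 19 of 19, among them Zg16 (-6.65 ± 0.36), Spink4 (-4.40 ± 0.13) and Klk1 (-3.51 ± 0.10), with a list median of -4.37 (fry adjusted p = 9.07e-19). All 24 tested enteroendocrine markers were also lower in stem cells, among them Sct (-3.93 ± 0.14), Chga (-5.20 ± 0.26) and Neurod1 (-4.76 ± 0.19), with a median of -5.04 (fry adjusted p = 6.48e-19). The counts adjusted over the list alone were the same for both lists. Atoh1, the transcription factor of secretory fate (-3.2 ± 0.11), and the Notch ligand gene Dll1 (-1.6 ± 0.07) were lower in stem cells. The gate gene Lgr5 differed by 3.57 ± 0.21, with wild-type means of 411 and 28.0 CPM. Epcam lay between 1925 and 2729 CPM and Cd24a between 198 and 338 CPM in all libraries, while Ptprc and Pecam1, genes of the sorted-out white blood and endothelial cells, reached at most 0.609 and 0.960 CPM.

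Markers of other mature cells were lower in stem cells too. All 22 tested Paneth cell markers fell (median -2.83, fry adjusted p = 2.89e-12; adjusted p = 0.215 with an estimated correlation), including Mptx1 (-5.11 ± 0.26) and Habp2 (-2.72 ± 0.15). Among 24 enterocyte markers, 19 were lower, including Sis (-4.31 ± 0.22) and Krt20 (-3.89 ± 0.19), 2 were higher and 3 did not pass (median -1.43, fry adjusted p = 2.84e-11; adjusted p = 0.215 with an estimated correlation). Tuft cell markers were lower for 11 of 12, including Avil (-2.5 ± 0.16) and Sh2d6 (-3.29 ± 0.35), with fry adjusted p = 4.01e-12 and adjusted p = 0.215 with an estimated correlation. Stem cells had higher MHC class II mRNA, 7 of 7 members, including H2-Aa (1.44 ± 0.31), Ciita (1.42 ± 0.17) and Cd74 (1.08 ± 0.20), with fry adjusted p = 4.89e-05 and adjusted p = 0.535 with an estimated correlation. Wnt targets were higher for 16 of 22, including Sp5 (2.30 ± 0.12) and Rnf43 (1.67 ± 0.10), and lower for 4, with fry adjusted p = 4.01e-12 and adjusted p = 0.202 with an estimated correlation. Every nuclear-encoded respiratory chain gene tested, 43 of 43, was lower in stem cells, including Sdhb (-0.73 ± 0.06) and Uqcrfs1 (-0.77 ± 0.06), with a median of -0.48, fry adjusted p = 1.5e-07 and adjusted p = 0.502 with an estimated correlation. In each of these lists the counts adjusted over the list alone were those over all genes. edgeR called 8315 of 13088 genes, 4259 higher and 4056 lower in stem cells. limma on the log2 TPM values called 9613, 7625 higher and 1988 lower, with the median of all genes moved from 0.02 to 0.27, and Cpt1a (-0.31 ± 0.08, adjusted p = 0.000755 by edgeR) lost its call there.

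To ask what the high-fat diet did in wild-type stem cells, the 4 high-fat libraries were compared with the 4 control libraries. The high-fat diet raised genes of fat use. Fabp1, a fatty acid binding protein, rose 14.8-fold from 13.7 ± 6.75 to 202.5 ± 80.8 CPM (SD, n = 4 and 4; log2 fold change 3.88 ± 0.43 SE, adjusted p = 0.00267). The lipoprotein gene Apoc2 (2.32 ± 0.30), the lipid-responsive transcription factor gene Creb3l3 (2.41 ± 0.32), the monoglyceride lipase gene Mgll (3.90 ± 0.74) and the retinol binding protein gene Rbp2 (2.87 ± 0.49) rose as well. So did the beta-oxidation genes Acadl (0.86 ± 0.17), Acadvl (0.70 ± 0.13), Hadhb (0.59 ± 0.12) and Hadha (0.50 ± 0.09). Nos2, the inducible nitric oxide synthase, fell from 14.1 ± 6.31 to 3.82 ± 0.727 CPM (-1.87 ± 0.36, adjusted p = 0.0409). For each called gene named in this comparison, the 2 groups' libraries did not overlap. Cpt1a itself was not called (0.42 ± 0.13, adjusted p = 0.18).

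By list, 8 of 35 PPAR target genes were higher and 27 did not pass, 17 higher and 1 lower adjusted over the list alone (median 0.50, fry adjusted p = 0.0096). Of 26 mitochondrial fatty acid oxidation genes, 4 were higher, 10 adjusted over the list alone (median 0.19, fry adjusted p = 0.0212; adjusted p = 0.0817 with an estimated correlation and 0.0505 with the column set as a block). Among 21 genes of fatty acid uptake and binding, 3 were higher, 5 higher and 2 lower adjusted over the list alone (median 0.10, fry adjusted p = 0.0139; adjusted p = 0.0765 with an estimated correlation). The PPAR list shares 14 of its genes with mitochondrial oxidation, 6 with peroxisomal oxidation and 7 with uptake and binding, so these results overlap.

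Several lists of differentiated cell markers were also higher on the high-fat diet in wild-type stem cells, though few single markers passed over all genes. All 17 tested goblet markers had a positive log2 fold change, with a median of 0.97, and 2 passed over all genes, Atoh1 (17.8 ± 2.85 to 36.9 ± 6.58 CPM; 1.04 ± 0.19, adjusted p = 0.0409) and Klk1 (0.96 ± 0.19, adjusted p = 0.0409). Adjusted over the list alone, 11 were higher and the list had a fry adjusted p = 0.0096. Of 24 enterocyte markers, 2 were higher, 6 adjusted over the list alone (median 0.65, fry adjusted p = 0.0096). Markers of the proximal small intestine had 1 of 10 higher, 2 adjusted over the list alone (median 0.41, fry adjusted p = 0.0096). No tuft marker of 6 passed over all genes and 1 did adjusted over the list alone (median 0.63, fry adjusted p = 0.0106; adjusted p = 0.0693 with an estimated correlation). The genes Reg4 (1.5 ± 0.29), Guca2b (1.51 ± 0.25) and Habp2 (1.11 ± 0.19) rose too. Paneth markers had a median of 0.79 that did not pass (fry adjusted p = 0.173). The mean log2 CPM of the enteroendocrine list was -0.0137 (SD 0.435) on the control diet and 0.395 (SD 0.491) on the high-fat diet. With the Xist level as a covariate that list did not pass (fry adjusted p = 0.348).

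MHC class II genes were lower on the high-fat diet in wild-type stem cells as a list. All 7 members had a negative log2 fold change (median -1.10), none passed over all genes and 6 were lower adjusted over the list alone (fry adjusted p = 0.032, and 0.016 to 0.106 without single libraries; adjusted p = 0.0817 with an estimated correlation). Cd74 averaged 1717 ± 55.4 CPM on the control diet and 810.3 ± 419 CPM on the high-fat diet (-1.10 ± 0.35, adjusted p = 0.246), and their activator Ciita differed by -0.98 ± 0.29 (adjusted p = 0.184). Stem cell markers did not pass as a list (median -0.10, fry adjusted p = 0.508), with Ascl2 at 0.57 ± 0.16 (adjusted p = 0.169) and Tnfrsf19 at -0.66 ± 0.17 (adjusted p = 0.114). Lgr5 averaged 455 ± 19.4 CPM on the control diet and 367 ± 111 CPM on the high-fat diet. All 43 nuclear respiratory chain genes had a positive log2 fold change, with a median of 0.13 (fry adjusted p = 0.499), and 22 of 30 proliferation genes did, with a median of 0.08 (fry adjusted p = 0.531).

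edgeR called 31 of 12409 genes in this comparison, 26 higher and 5 lower, and DESeq2 called 180, 104 higher and 76 lower. The share of higher genes was not stable. Without single libraries the count ran from 5 to 25, with 6 higher and 9 lower without high-fat library c, and a fit of only the 8 libraries called 2, of which 1 (Mgll) was among the 31. With a per-library score of goblet, Paneth and enteroendocrine markers as a covariate 17 were higher and 15 lower, and 7 of the 31 stayed called, among them Fabp1, Apoc2, Acadvl, Ly6e and Nos2.

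In Cpt1a-deficient stem cells the same diet contrast asked whether the response needed the enzyme. Here too the high-fat diet raised genes of fat handling. Fabp1 rose 8.96-fold from 78.7 ± 32.9 to 704 ± 202 CPM (SD, n = 4 and 4; log2 fold change 3.16 ± 0.39 SE, adjusted p = 0.013). Me1, the cytosolic malic enzyme, rose from 4.88 ± 2.69 to 25.2 ± 4.65 CPM (2.35 ± 0.31, adjusted p = 0.00592). Acaa1b (2.86 ± 0.51), Tm4sf4 (1.27 ± 0.19), Retsat (0.92 ± 0.15), Galnt12 (0.86 ± 0.15), Hadhb (0.68 ± 0.11) and Hsdl2 (0.65 ± 0.12) completed the 8 genes called, all higher. PPAR targets had 3 of 35 higher, 16 adjusted over the list alone (median 0.43, fry adjusted p = 0.0133). Mitochondrial oxidation genes had 1 of 26 higher, 9 adjusted over the list alone (median 0.15, fry adjusted p = 0.0371), and uptake and binding genes 1 of 21, 5 adjusted over the list alone (median 0.17, fry adjusted p = 0.0133). With the column set as a block none of these 3 lists passed (0.0519, 0.0821 and 0.0519). Goblet markers were positive for 17 of 17 but did not pass (median 0.64, fry adjusted p = 0.0634), and MHC class II genes did not pass (median -0.68, fry adjusted p = 0.403). The called genes numbered 8 of 12409 by edgeR and 43 by DESeq2, 33 higher and 10 lower. Without single libraries the count ran from 0 to 14, every named gene lost its call in at least 1 of those 8 fits, and no gene passed with the secretory marker score as a covariate.

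The comparison of Cpt1a-deficient with wild-type stem cells on the high-fat diet asked what loss of the enzyme did under fat feeding. Genes of fatty acid oxidation were higher in the deficient cells, not lower. Acadl, the long-chain acyl-CoA dehydrogenase, stood at 341 ± 37.3 against 145 ± 32.5 CPM (SD, n = 4 and 4; log2 fold change 1.26 ± 0.17 SE, adjusted p = 0.00134). Both subunits of the trifunctional protein were higher, Hadha by 0.85 ± 0.09 (adjusted p = 7.19e-05) and Hadhb by 1.04 ± 0.12 (adjusted p = 0.000139). Hsdl2 (1.33 ± 0.12), Eci2 (1.26 ± 0.17), Creb3l3 (1.95 ± 0.27), Me1 (2.17 ± 0.30), Slc22a3 (1.88 ± 0.26), Tm4sf4 (1.39 ± 0.19) and the acyl-CoA thioesterase genes Acot1 (2.02 ± 0.34), Acot2 (1.74 ± 0.29) and Acot4 (1.08 ± 0.17) were higher as well. Estimated counts divide reads among near-identical copies, so the values of Acot1, Acot2, Acot4, Acaa1b, Cyp4a10, Entpd4 and Scd2 are uncertain throughout. Acacb, the acetyl-CoA carboxylase whose product inhibits Cpt1 enzymes, was higher by 1.97 ± 0.32 (adjusted p = 0.00519). Apart from Cpt1a, the lower genes included the desaturase gene Scd2 (51.9 ± 33.8 to 8.54 ± 2.76 CPM; -2.59 ± 0.48, adjusted p = 0.0351), the pyruvate carboxylase gene Pcx (-0.91 ± 0.19, adjusted p = 0.0363), Slc25a29 (-1.04 ± 0.21), Tlr1 (-1.48 ± 0.27), Clca4b (-1.25 ± 0.21) and BC064078 (-1.09 ± 0.15).

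PPAR targets had 13 of 35 higher and 1 lower, Cpt1a, with 26 higher and 1 lower adjusted over the list alone (median 0.74, fry adjusted p = 0.00134). Of 26 mitochondrial oxidation genes, 8 were higher and 1, Cpt1a, lower, with 12 and 1 adjusted over the list alone (median 0.26, fry adjusted p = 0.0105). Peroxisomal oxidation genes had 4 of 19 higher, including Ech1 (0.66 ± 0.14), Crot (0.54 ± 0.11) and Abcd3 (0.48 ± 0.09), and 10 adjusted over the list alone (median 0.27, fry adjusted p = 0.00253). Uptake and binding genes had 2 of 21 higher, 6 higher and 1 lower adjusted over the list alone (median 0.05, fry adjusted p = 0.018; 0.051 with the column set as a block). Stem cell markers (median -0.02, fry adjusted p = 0.588), goblet markers (-0.06, fry adjusted p = 0.873), enterocyte markers (-0.41, fry adjusted p = 0.675) and MHC class II genes (-0.02, fry adjusted p = 0.873) did not pass. edgeR called 55 of 12409 genes, 42 higher and 13 lower, and DESeq2 106. Another split of the same 8 libraries, which divided both genotypes by the same sets of columns, gave 1205, so these splits, which ignore the sets, cannot exclude chance. Without single libraries the count ran from 30 to 81, a fit of only these 8 libraries called 25, and Cpt1a, Hadha, Hadhb, Acadl, Hsdl2 and Eci2 stayed called without each library in turn.

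On the control diet the deficient stem cells were compared with wild-type ones, which asked what loss of the enzyme did without fat feeding. The same kind of genes stood higher. Creb3l3 was at 58.2 ± 11.5 against 6.81 ± 2.85 CPM (SD, n = 4 and 4; log2 fold change 3.12 ± 0.32 SE, adjusted p = 0.000164). Mgll (4.17 ± 0.73), Fabp1 (2.53 ± 0.43), Acacb (2.33 ± 0.39), Acot1 (2.29 ± 0.35), Slc22a3 (2.04 ± 0.30), Acadl (1.28 ± 0.17), Hsdl2 (1.27 ± 0.12), the carnitine-acylcarnitine carrier gene Slc25a20 (1.14 ± 0.16), Hadhb (0.95 ± 0.12) and Hadha (0.91 ± 0.09) were higher. The genes lower, apart from Cpt1a, were Bsdc1 (-0.58 ± 0.10) and BC064078 (-1.04 ± 0.15). PPAR targets had 13 of 35 higher and 1 lower, 22 and 1 adjusted over the list alone (median 0.72, fry adjusted p = 0.00367). Mitochondrial oxidation genes had 9 of 26 higher and 1 lower, 12 and 1 adjusted over the list alone (median 0.19, fry adjusted p = 0.0204; 0.0756 with the column set as a block). Peroxisomal oxidation genes had 1 of 19 higher, 10 adjusted over the list alone (median 0.26, fry adjusted p = 0.00415). Stem cell markers did not pass (median -0.07, fry adjusted p = 0.782). edgeR called 30 of 12409 genes, 27 higher and 3 lower, and DESeq2 60, 46 higher and 14 lower. Without single libraries the count ran from 14 to 33, with Cpt1a, Creb3l3, Acadl, Hadha and Hadhb called each time.

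Whether the diet effect in stem cells differed between the genotypes was tested as an interaction. No gene passed in edgeR, with 444 of 12409 at an unadjusted p under 0.05, and none passed in DESeq2 or in limma. PPAR targets as a list had a median of -0.01 (fry adjusted p = 0.978). None of the 36 lists passed. In simulated data for this test, 50% of genes changed 2-fold and 76% of genes changed 4-fold were recovered. Differences between the genotypes of these sizes, and smaller ones more often, could thus be missed.

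**Figure D2:**
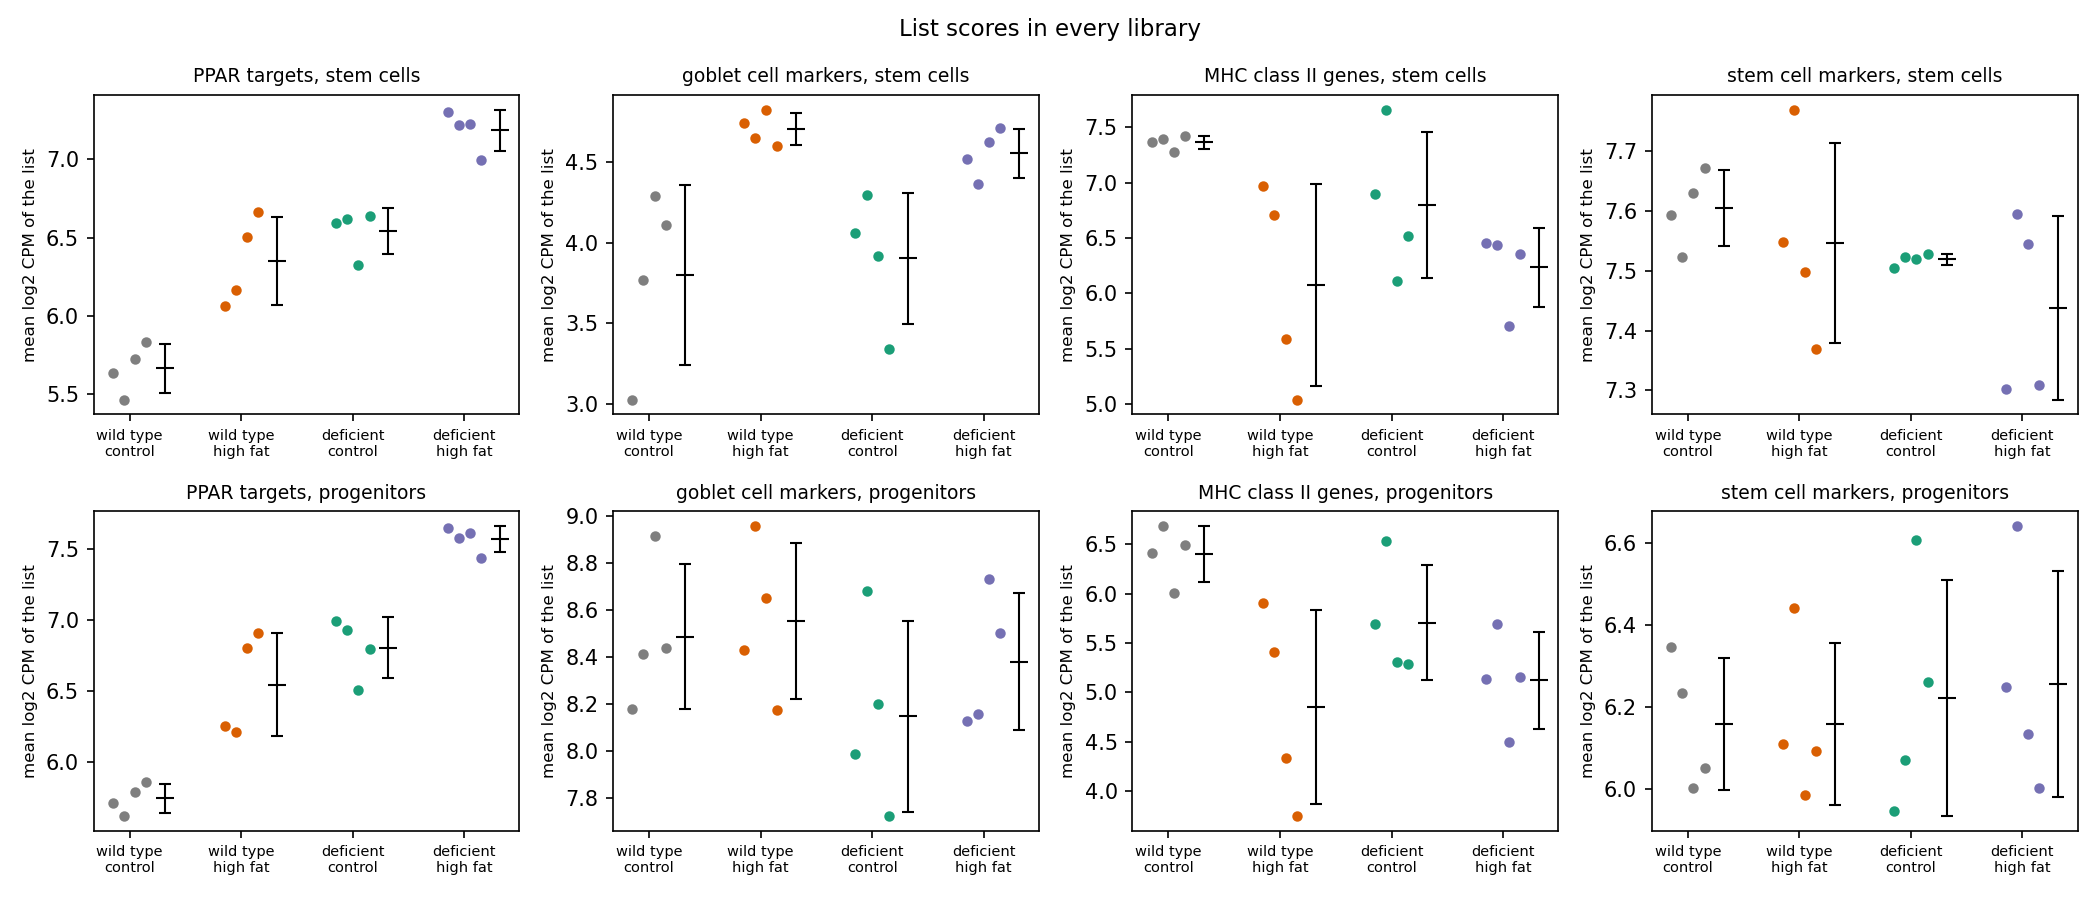
Mean log2 CPM (vertical axes) of the PPAR target, goblet, MHC class II and stem cell marker lists in every library of stem cells (top) and progenitors (bottom) by genotype and diet (horizontal axes), with bars for the mean and SD of 4 libraries. The PPAR score in stem cells averaged 5.67 in wild type on the control diet, 6.35 in wild type on the high-fat diet, 6.54 in deficient cells on the control diet and 7.18 in deficient cells on the high-fat diet.

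Next, the genes that the diet changed in wild-type cells were followed into the deficient cells. In stem cells, 7 of the 26 genes raised by the diet were also higher in deficient cells on the high-fat diet, including Acadl, Acadvl, Creb3l3, Hadha, Hadhb and Slc22a3, and none was lower there. With the control diet, 9 of the 26 were also higher in deficient cells, including Fabp1 and Mgll. Each of these pairs of effects shares 1 group of wild-type libraries, so the lists are not independent and no chance value is given for the overlaps. In progenitors, 8 of the 11 genes raised by the diet were higher in deficient cells on the high-fat diet and none was lower. Across 12408 genes, which are not independent replicates, the diet effect in wild-type stem cells and the genotype effect on the high-fat diet had r = -0.264. Unchanged groups that share the wild-type high-fat libraries gave a mean r of -0.495 with 95% limits of -0.746 to -0.135, which hold the observed value. With those libraries split into 2 and 2 the observed mean over the splits was 0.0622. Single simulated splits ran from -0.627 at the lowest to 0.756 at the highest, which is wider than 95% limits of such a mean would be. The covariance was -0.0285 against -0.0405 simulated. In progenitors r was -0.208 against -0.486 simulated (95% limits -0.752 to -0.126). With the libraries split the mean was 0.0994 (lowest and highest single simulated split -0.582 and 0.598). The diet effects in the 2 genotypes, which share no library, had r = 0.386 in stem cells, within the simulated 95% limits of -0.421 to 0.453, and 0.284 in progenitors, within -0.421 to 0.405. Among genes with a mean log2 CPM of at least 3, r was 0.515 in stem cells and 0.402 in progenitors. The first lay above the 95% limits of -0.555 to 0.496, which were not adjusted over the correlations compared. The highest simulated r was 1, an exact match that centred values can give by cancellation, so it sets no bound for real groups. The second lay within -0.502 to 0.447. All these simulations drew libraries without regard to the column sets, whose libraries tended to deviate together. Their limits may thus be too wide, and a value within them is not shown to come from unchanged groups.

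In wild-type progenitors the high-fat diet again raised genes of fat use. Acadl rose from 99.6 ± 7.97 to 181 ± 32.9 CPM (SD, n = 4 and 4; log2 fold change 0.86 ± 0.14 SE, adjusted p = 0.0188), and Acacb (2.68 ± 0.49), Acaa1b (2.53 ± 0.40), Hsdl2 (0.93 ± 0.16), the fatty acid transporter gene Slc27a4 (0.83 ± 0.15), Slc25a20 (0.82 ± 0.13), Mettl7b (0.80 ± 0.14), Acaa2 (0.68 ± 0.11) and Hadha (0.52 ± 0.09) rose too. PPAR targets had 6 of 35 higher, 21 adjusted over the list alone (median 0.52, fry adjusted p = 0.0459; adjusted p = 0.0551 with an estimated correlation). Uptake and binding genes had 1 of 21 higher, 5 higher and 1 lower adjusted over the list alone (median 0.26), with the same 2 adjusted p values. Neither list passed with the column set as a block (0.0814 and 0.0858). MHC class II genes had 7 of 7 negative, none passed over all genes and 7 were lower adjusted over the list alone (median -1.44, fry adjusted p = 0.0459; adjusted p = 0.0551 with an estimated correlation). Cd74 averaged 940.1 ± 98.2 CPM on the control diet and 320.1 ± 204 CPM on the high-fat diet (-1.56 ± 0.44, adjusted p = 0.437). Goblet markers (median 0.12, fry adjusted p = 0.863) and enterocyte markers (0.32, fry adjusted p = 0.358) did not pass. edgeR called 11 of 12460 genes, all higher, and DESeq2 47, 37 higher and 10 lower, but with the column set as a block edgeR called 0, with 1037 at an unadjusted p under 0.05. Without single libraries the count ran from 0 to 16, and each of the 9 called genes named here lost its call at least once.

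In deficient progenitors too, the high-fat diet was compared with its control. Cyp4a10, a fatty acid omega-hydroxylase, rose from 10.7 ± 6.24 to 89.0 ± 18.1 CPM (SD, n = 4 and 4; 3.06 ± 0.45 SE, adjusted p = 0.00779), and Me1 from 18.5 ± 9.70 to 119 ± 23.0 CPM (2.70 ± 0.33, adjusted p = 0.00338). Acaa1b (2.5 ± 0.28), Mgll (1.92 ± 0.33), Acacb (1.80 ± 0.32), Retsat (0.98 ± 0.13), Acadl (0.83 ± 0.14), Slc25a20 (0.77 ± 0.13), Acadvl (0.69 ± 0.11), Hadhb (0.68 ± 0.10) and Ech1 (0.63 ± 0.10) rose with them. Oxct1, the enzyme that starts ketone body breakdown, fell from 101 ± 2.32 to 54.8 ± 4.45 CPM (-0.86 ± 0.09, adjusted p = 0.000322). Scd2 (-2.43 ± 0.44), the ileal bile acid binding protein gene Fabp6 (-2.95 ± 0.59), the folate enzyme gene Aldh1l1 (-0.75 ± 0.15) and the selenium carrier gene Selenop (-0.62 ± 0.12) fell as well. PPAR targets had 12 of 35 higher, 21 adjusted over the list alone (median 0.54, fry adjusted p = 0.0119; adjusted p = 0.056 with an estimated correlation and 0.0512 with the column set as a block), and no other list passed. MHC class II genes had a median of -0.77 (fry adjusted p = 0.597). edgeR called 39 of 12460 genes, 30 higher and 9 lower, and DESeq2 118, 73 higher and 45 lower. The count ran from 16 to 84 when each library was left out in turn.

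On the high-fat diet, deficient progenitors differed from wild-type ones in the largest number of genes among the 8 comparisons within a population by edgeR, DESeq2 and limma. This rank did not hold with the column set as a block, where edgeR called 99 genes here and 100 for diet in wild-type stem cells. Pdk4, the kinase that shuts off pyruvate dehydrogenase, stood at 101 ± 33.2 against 14 ± 11.9 CPM (SD, n = 4 and 4; log2 fold change 2.92 ± 0.54 SE, adjusted p = 0.0298), and Angptl4, a lipoprotein lipase inhibitor, at 147 ± 35.9 against 23.5 ± 16.5 CPM (2.69 ± 0.49, adjusted p = 0.0268). Acot1 (2.96 ± 0.30), Acaa1b (2.30 ± 0.28), Me1 (2.25 ± 0.33), Acacb (2.09 ± 0.33), Slc25a20 (1.16 ± 0.13), Hadhb (1.09 ± 0.10), Hadha (0.79 ± 0.09), the lipid droplet gene Plin2 (0.57 ± 0.11) and the catalase gene Cat (0.51 ± 0.11) were higher. Lower genes were Oxct1 (54.8 ± 4.45 against 102 ± 5.76 CPM; -0.89 ± 0.09, adjusted p = 9.33e-05), Scd2 (-2.85 ± 0.43), the stress gene Sesn1 (-0.83 ± 0.11), the glucose transporter gene Slc2a1 (-0.62 ± 0.13), the sterol transporter gene Abcg5 (-0.82 ± 0.15), the acetoacetyl-CoA synthetase gene Aacs (-0.58 ± 0.12) and Aldh1l1 (-0.85 ± 0.15). PPAR targets had 19 of 35 higher and 1, Cpt1a, lower, 31 and 1 adjusted over the list alone (median 0.79, fry adjusted p = 0.000783). Mitochondrial oxidation genes had 9 of 26 higher and 1 lower, 13 and 1 adjusted over the list alone (median 0.29), and peroxisomal ones 5 of 19 higher, 9 higher and 1 lower adjusted over the list alone (median 0.31). Both had fry adjusted p = 0.0184 and adjusted p = 0.141 with an estimated correlation, and neither passed with the column set as a block (0.0668 and 0.0624). edgeR called 88 of 12460 genes, 59 higher and 29 lower, and DESeq2 190, 101 higher and 89 lower. Leaving out 1 library gave 35 to 90 genes.

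Deficient progenitors on the control diet were compared with wild-type ones. Pdk4 (log2 fold change 3.48 ± 0.62 SE, n = 4 and 4, adjusted p = 0.0425), Acot1 (3.44 ± 0.34), Acacb (2.98 ± 0.48), Angptl4 (2.85 ± 0.51), Creb3l3 (2.5 ± 0.42), Slc25a20 (1.20 ± 0.13), Acadl (1.13 ± 0.14), Acaa2 (0.90 ± 0.11), Hadha (0.78 ± 0.09) and the peroxisome gene Pex11a (0.69 ± 0.14) were higher. Oxct1 (-0.46 ± 0.09, adjusted p = 0.0425) and Sesn1 (-0.52 ± 0.11, adjusted p = 0.0425) were lower, besides Cpt1a. PPAR targets had 17 of 35 higher and 1 lower, 25 and 1 adjusted over the list alone (median 0.69, fry adjusted p = 0.00487), and no other list passed. Stem cell markers had a median of 0.05 (fry adjusted p = 0.901). edgeR called 32 of 12460 genes, 28 higher and 4 lower, and DESeq2 83, 59 higher and 24 lower. With 1 library left out, 17 to 49 were called.

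The 2 populations shared many of the called genes. On the high-fat diet 30 genes were higher and 4 lower in deficient cells of both, where independent lists would share 0.207 and 0.0271, and on the control diet 16 were higher in both (expected 0.0631). The shared lower genes were Scd2, Entpd4, Rnf145 and BC064078. The diet raised 3 genes in wild-type cells of both populations, including Acadl and Hadha (expected 0.0239), and 6 in deficient cells of both, Acaa1b, Hadhb, Hsdl2, Me1, Retsat and Tm4sf4 (expected 0.0194). Genes named here for being shared were chosen after their values were seen. The labels do not say whether stem cells and progenitors came from the same mice, so the lists cannot be taken as independent.

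In progenitors the interaction of diet and genotype gave 0 genes in edgeR, with 561 of 12460 at an unadjusted p under 0.05, and 0 in DESeq2 and limma. PPAR targets had a median of -0.03 (fry adjusted p = 0.986). Differences between the populations were tested as well. No gene passed for the wild-type diet effect in stem cells against progenitors, with 423 of 13088 at an unadjusted p under 0.05 in edgeR and 1 called by DESeq2. Atoh1 had a difference of 0.95 ± 0.30 (adjusted p = 1) and Klk1 of 0.76 ± 0.27 (adjusted p = 1), and the goblet list had a median of 0.76 (fry adjusted p = 0.534), so this model, which pairs no libraries, did not show that the goblet marker change in stem cells differed from that in progenitors. A fit that pairs libraries by column set is given below and did call that difference. For the genotype effect on the high-fat diet, edgeR called 0 of 13088 genes, with 331 at an unadjusted p under 0.05, and DESeq2 and limma 0. None of the 36 lists passed in these 3 tests of difference without that pairing.

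**Figure D3:**
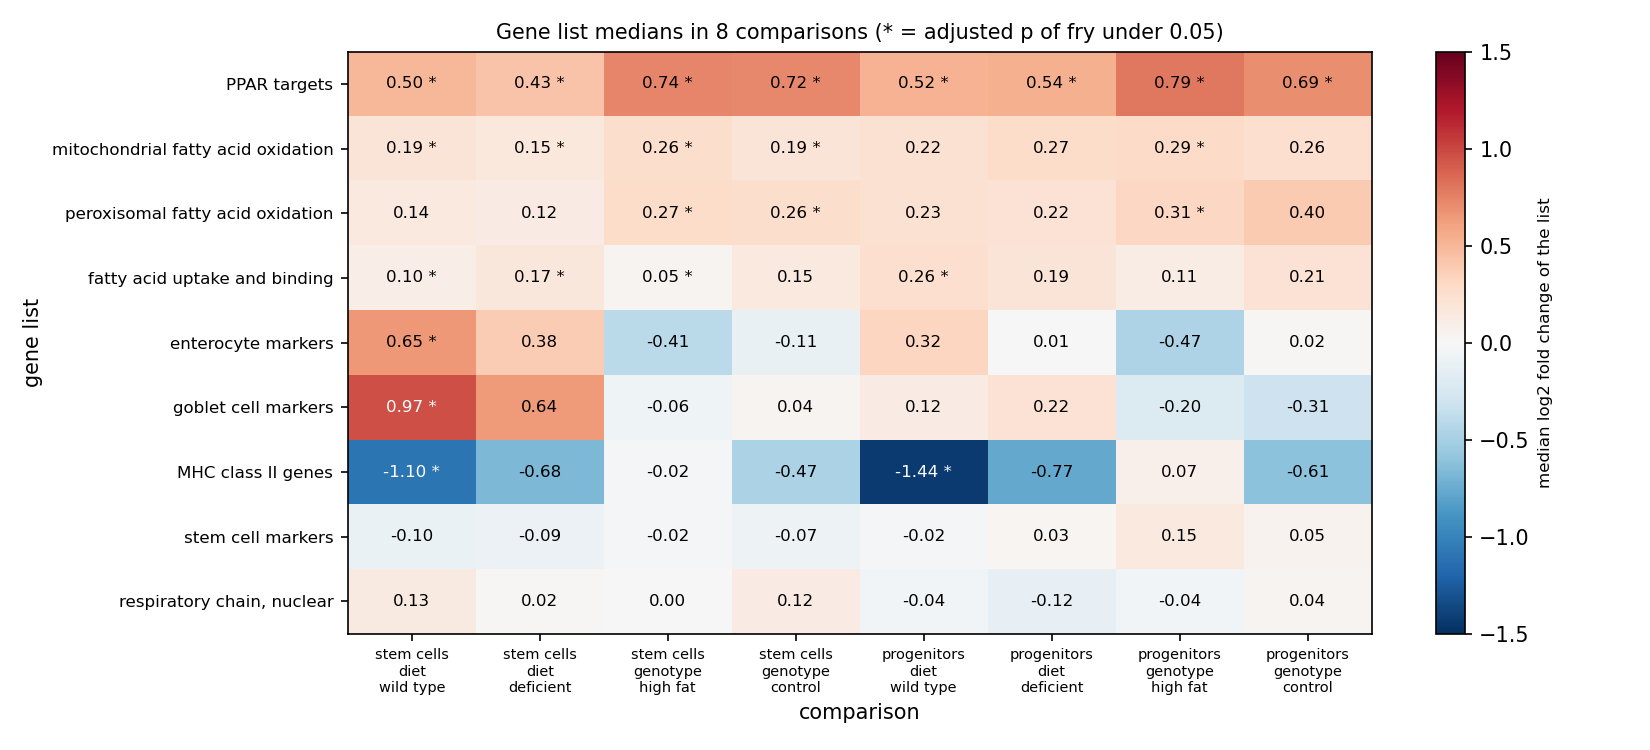
Median log2 fold change (colour and printed value) of 9 gene lists (vertical axis) in 8 comparisons (horizontal axis), where an asterisk marks a fry adjusted p under 0.05. The PPAR target list is marked in all 8 comparisons, with medians of 0.43 to 0.79, but did not pass with an estimated correlation for diet in wild-type and deficient progenitors (adjusted p = 0.0551 and 0.056), nor with the column set as a block for these 2 and for diet in deficient stem cells, while stem cell markers are marked in none.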

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

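The tests of the 3 patterns below were chosen after the results were seen, except the test of whether Cpt1a loss on the control diet acts on the same genes as the high-fat diet.

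Among 144 groups of 4 libraries looked at for genes and lists of the text, 6 had 1 library far from the other 3 by Dixon's ratio (gap over range), and chance gives about 1 group in 20. In deficient stem cells on the control diet, library c had the lowest PPAR target score, 6.33 against 6.59 to 6.64 (ratio 0.850). In deficient stem cells on the high-fat diet, library c had an MHC class II score of 5.71 against 6.35 to 6.45 (0.866). Library d of deficient progenitors on the control diet had 97.2 CPM of Oxct1 against 101.8 to 101.9 (0.971). Library a of wild-type stem cells on the control diet had 174 CPM of H2-Aa against 184 to 186 (0.888). Ptprc had reads in 1 library only of deficient stem cells on the control diet (0.177 CPM, ratio 1) and of wild-type progenitors on the high-fat diet (0.172 CPM, ratio 1). In the reported edgeR fits no gene passed the tests of differences between the genotypes or populations, with the counts at an unadjusted p given above. Some edgeR fits given below, with a block or without 1 library, did call genes.

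PPAR targets were higher in Cpt1a-deficient stem cells on both diets. Variants linked to the floxed Cpt1a locus that act on genes near them are argued against for the 15 called targets. Of these, 0% lie on its chromosome 19, and they lie on 12 chromosomes. A linked variant that acts on genes of other chromosomes could not be seen this way and stays open. The genes lower in deficient cells, among them Scd2 and Pcx, were not part of this check, so a linked variant stays open for them too. More enterocytes in the gate are argued against as well, since enterocyte markers that are not PPAR targets had a median of -0.49 on the high-fat diet (interquartile range 0.896) against 0.75 for the targets. Whether Cpt1a loss on the control diet acts on the same genes as the diet stays open: with the control libraries split, r was 0.0718, and simulated unchanged groups ranged from -0.634 to 0.668, so the bound written beforehand could exclude nothing at this spread. A candidate explanation is that fatty acids not admitted to mitochondria act on PPAR receptors, which was not tested, and no lipid was measured.

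Goblet and enterocyte markers were higher on the high-fat diet in wild-type stem cells. Library differences that follow Xist are argued against as the cause by the design, since each group holds 2 libraries with Xist and 2 with Ddx3y. The goblet median was positive among both, 1.12 with Xist (fry adjusted p = 0.0155) and 0.62 with Ddx3y (0.102). These medians are no separate test, because both kinds make up the rise already seen over all libraries. Enterocyte medians were 0.84 (0.0166) and 0.34 (0.215), and the differences did not pass (0.5 for goblet and 0.29 for enterocyte markers). More progenitors inside the stem cell gate stay open: the high-fat libraries' rise equals a progenitor share of 2.49% from goblet, 0.617% from enteroendocrine, 5.82% from Paneth and 15.4% from tuft markers, and with the same difference in the control libraries taken off, the goblet share lies 1.55 points (SD 1.39) above the enteroendocrine one, 14 (SD 6.75) under the tuft one and 12.7 (SD 10.6) under that of enterocyte markers other than PPAR targets. The tuft share speaks against 1 common share, but these markers had a median of 5.63 counts per control library, too few to exclude it, and a change of the stem cells themselves by the diet was not tested.

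MHC class II genes were lower on the high-fat diet in wild-type cells, but did not pass with an estimated correlation (adjusted p = 0.0817 in stem cells and 0.0551 in progenitors). Fewer white blood cells in the gate are argued against, since Ptprc was 0.0504% of H2-Aa on the control diet in stem cells (0.0919 against 182 CPM), with Lyz2 at 0.134 and Tyrobp at 0 CPM. Whether 1 library decides the fall in stem cells stays open: the highest fry p without any of the 8 libraries was 0.0293 before adjustment, but the adjusted p rose above 0.05 without high-fat library c (0.0966) or d (0.106) or control library a (0.0579), b (0.0633) or d (0.0667). An effect of the diet on the epithelial cells may remain, as would animal or housing differences, which the labels do not give.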

How the results depend on the processing

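The fits with the column set as a block, with the Xist level or the secretory marker score as a covariate and within libraries with Xist or Ddx3y were chosen after the results were seen. No paired analysis was possible by labelled replicate number, because the columns carry none and the labels do not link libraries to animals. The planned sex term, replicate block, fits of female or male libraries by label, fry with the block and left-out replicate numbers could not be fitted for the same reason, and the fits without a sex term equal the reported ones. No named gene changed direction. Of the fits of genes called for diet or genotype, 760 kept and 496 lost the call (39.5%) without 1 library, and 1420 kept and 217 lost it under the other alternatives. For stem cells against progenitors 2368 kept and 0 lost it without 1 library. At this depth, changes under 2-fold are often missed, and some larger ones are too. Unless said otherwise, the cause was not tested.

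With DESeq2 the counts for diet in wild-type and deficient cells and for genotype on high-fat and control diet were 180, 43, 106 and 60 in stem cells and 47, 118, 190 and 83 in progenitors, and 1 for the diet effect between populations. limma gave 19 for diet in wild-type stem cells. No filter gave 56 and 22 for diet in wild-type and deficient stem cells and 18 and 67 in progenitors, and protein-coding genes alone 55 and 13 in stem cells. All 32 libraries in 1 model gave 61, 21 and, in wild-type progenitors, 22. Only the 8 libraries gave 2, 18 and, for genotype on the high-fat diet, 25 in stem cells, and 4 for diet in wild-type progenitors, with fewer libraries to estimate the spread. The Xist covariate gave 57 in wild-type stem cells and 7 in wild-type progenitors, and the secretory score 0 in deficient stem cells. Libraries with Xist gave 6 in wild-type stem cells (5 higher, 1 lower) and 0 in wild-type progenitors. Those with Ddx3y gave 25 (8 higher, 17 lower, where the reported 31 are 26 higher and 5 lower) and 36.

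The columns run in 4 sets, and what a set shares is not stated. The order of the columns is also the order of the labelled libraries. In that order, sets a and b, with more Xist, fall on the female labels and sets c and d on the male ones. The sets may therefore be the labelled replicates, which the column names do not say. Deviations from the group means correlated by 0.177 on average (lowest 0.0327) between stem cell libraries of a set and by 0.119 (lowest -0.0921) in progenitors. Between sets the means were -0.059 and -0.0396, which follow from the means within sets because each group was centred, and add no evidence. In all, 16 of 16 and 13 of 16 libraries correlated best with their own set, so libraries of a set tended to deviate together. The reported tests treat them as independent. Between stem cells and progenitors of 1 diet and genotype the mean was 0.209 (lowest 0.0981), with 15 of 16 best with their own set. With the set as a block the counts were 100 (60 higher, 40 lower), 15, 75 and 24 in stem cells and 0 (1037 at an unadjusted p under 0.05), 54, 99 and 28 in progenitors, in the order used above for DESeq2. The lists past the threshold numbered 8, 0, 4 and 2, then 1, 0, 1 and 1. PPAR targets were no longer called for diet in deficient stem cells or in either genotype of progenitors, with the values given above, while MHC class II genes kept the call in wild-type stem cells (0.0236) and progenitors (0.0252). With the set within each diet and genotype as a block, the goblet list passed for the diet effect in stem cells against progenitors (median 0.76, fry adjusted p = 0.0388, against 0.534 as reported). That fit called 2 genes for this difference (Gm10222 and Trp53inp1) and 2 for the genotype effect (Gm10222 and Acot1), named after their values were seen.

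Of the lists, 9, 3, 4, 4 and 0 passed in the 5 stem cell tests (diet in wild-type and deficient cells, genotype on high-fat and control diet, interaction), 3, 1, 3, 1 and 0 in progenitors and 29 between populations. camera with an estimated correlation passed 5, 3, 4, 4 and 0, then 0, 0, 1, 1 and 0, and 3. With the preset correlation it passed 20, 16, 11, 11 and 8, then 15, 16, 9, 11 and 7, 20 between populations, and 6 and 3 for the differences of the diet and genotype effects. The correlation of the diet effect with the genotype effect on the high-fat diet turned from -0.264 to 0.0622 in stem cells and from -0.208 to 0.0994 in progenitors with the shared libraries split, because sharing them makes it negative. Among genes with a mean log2 CPM of at least 3 it was -0.206 and -0.0852, and that of the 2 diet effects 0.515, above its simulated limit of 0.496, and 0.402.

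Without single libraries (leave-one-out) the counts ran as follows, with each library that moved a count over 1.5 times. Diet in wild-type stem cells: 5 to 25 (high-fat a 8, c 15, d 6; control a 5, b 13, c 5, d 10). Diet in deficient stem cells: 0 to 14 (high-fat a 1, b 5, c 2, d 14; control a 2, c 2, d 0). Genotype on the high-fat diet in stem cells: 30 to 81 (deficient b 32, c 35, wild type a 30, b 31). On the control diet: 14 to 33 (deficient a 17, b 15, wild type a 16, c 14, d 15). Diet in wild-type progenitors: 0 to 16 (high-fat c 1, d 1, control a 0, b 1, c 0, d 4). Diet in deficient progenitors: 16 to 84 (high-fat a 20, b 19, c 23, control a 22, c 84, d 16). Genotype on the high-fat diet in progenitors: 35 to 90 (deficient a 48, b 35, wild type a 38, b 45, c 54). On the control diet: 17 to 49 (deficient a 17, b 18, c 49, wild type b 19, c 18, d 20). The interaction gave 0 in stem cells and 0 to 1 in progenitors (1 without deficient high-fat a), stem cells against progenitors 8198 to 8577, and both differences between populations 0. The correlation of the diet effect with the genotype effect ran from -0.355 to -0.218 in stem cells and -0.325 to -0.171 in progenitors, and with the diet effect in deficient cells from 0.328 to 0.406 and 0.226 to 0.328.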

Other observations

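The comparison of libraries with Xist and libraries with Ddx3y and the splits within column sets were chosen after the results were seen, and the other splits of the libraries were planned.

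Other lists differed between stem cells and progenitors, with fry adjusted p and then adjusted p with an estimated correlation. Histone acetylation enzymes were higher for 11 of 19 in stem cells (1.53e-10, 0.215), including Hdac5 (0.96 ± 0.10). Sterol synthesis genes were lower for 23 of 24 (1.32e-09, 0.341), including Lss (-1.15 ± 0.11), tricarboxylic acid cycle genes for 21 of 24 (8.33e-10, 0.372), including Cs (-0.72 ± 0.05), and glycolysis genes for 15 of 20, with 3 higher (7.65e-11, 0.256), including Ldha (-1.32 ± 0.08). Stress response genes were lower for 16 of 23 and higher for 5 (1.62e-08, 0.439), including Hspa5 (-1.04 ± 0.08), and antioxidant genes lower for 11 of 19 and higher for 2 (2.34e-09, 0.372), including Nqo1 (-2.31 ± 0.15). PPAR targets were lower for 20 of 35 and higher for 8 (0.02, 0.894). Notch genes were higher for 5 of 11 and lower for 4, with a positive median of 0.28 and a negative test (0.00156, 0.877). Proliferation genes did not pass (0.222).

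The fall of MHC class II genes on the high-fat diet may be larger in libraries with Ddx3y, which the labels' balance of sexes allows to be asked. In wild-type stem cells the list median was -0.58 with Xist (fry adjusted p = 0.268) and -1.91 with Ddx3y (0.00288), with 2 libraries per group, and in progenitors -1.04 (0.166) and -2.21 (0.00629). The difference did not pass (stem cells, fry adjusted p = 0.125; progenitors, 0.362), so it is not shown to differ and stays open. In stem cells 2 other lists had a smaller p for the difference and did not pass either. Paneth markers had a median of 2.84 with Xist (0.0155) and -0.06 with Ddx3y (0.945), with 0.0864 for the difference, and antimicrobial genes 0.10 (0.522) and -1.47 (0.0225), also with 0.0864. By edgeR, 0 genes passed for the difference in either population, with 364 at an unadjusted p under 0.05 in stem cells and 495 in progenitors; it was not run in other tools.

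Other splits of the same libraries were counted for each comparison, without regard to the column sets. The real split gave the most genes for diet in wild-type (31, highest other split 3) and deficient stem cells (8, 0). It also did for genotype on the control diet in stem cells (30, 1) and diet in wild-type (11, 1) and deficient progenitors (39, 4). The same held for genotype on the high-fat (88, 1) and control diet in progenitors (32, 1), and stem cells against progenitors (8315, 2572). With the column set as a block, diet in wild-type progenitors gave 0 genes. A real split alone at the top is 1 of 35, or 1 of 60 between populations, not adjusted over the comparisons. These ranks argue against chance but do not exclude it. For genotype on the high-fat diet in stem cells (55), the splits do not argue against chance, since 2 of 35 gave as many and the other gave 1205. That split sets libraries a and d of both groups against b and c, so it points to a structure shared by both groups that does not follow Xist, and the labels give no batch. With the column set as a block, chosen after this was seen, the count was 75, and the 7 other splits that swap the groups within sets gave 0. For diet in wild-type and deficient cells and genotype on the control diet such splits gave 100 (highest other 2), 15 (0) and 24 (0) in stem cells, and in progenitors 0 (0), 54 (6) and 28 (0), with 99 (0) for genotype on the high-fat diet. These 8 splits are too few for a share under 0.05. For the tests that called 0 genes in edgeR all splits gave as many, 100 of 100 for each interaction (highest other 603 in stem cells and 22 in progenitors) and 60 of 60 for each difference between populations (35 for diet, 34 for genotype). The 603 points to a structure of the stem cell libraries too.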
